A study of Mus musculus with 24 samples.

How the data were processed

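RNA from both dorsal hippocampi of 24 mice was sequenced, with 6 animals in each of 4 groups defined by genotype (wild type or Baf53b+/-) and condition (home cage or killed 30 minutes after object location memory training). Per the labels' protocols, RNA was isolated on RNeasy columns, libraries were made with the TruSeq RNA v2 kit, which does not keep strand, and single-end reads of 50 cycles came from an Illumina HiSeq instrument. The labels also state that the libraries were pooled into 4 multiplexes with all behavioural groups on every flow cell. Which pool held which animal is not given in the sources used here, so no batch could be fitted. Alignment was to mm9, and the submitters' processing notes name CASAVA 1.8.2 and Bowtie 0.12.8. The authors deposited 1 table of RPKM values with 19661 genes in lines, their mm9 positions and 1 column per animal, so replicates were not pooled. The annotation, the read total in the RPKM and the handling of reads that match several genes are not given in the sources used here, and reads of overlapping or antisense genes cannot be told apart without strand. Of the names, 18 had been turned into dates and 12 were repeated; these stayed in as separate entries under their positions.

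Depth was recovered from the values. In 971 single-exon genes with up to 30 reads, a library's RPKM values are multiples of what 1 read is worth for the gene's length. Multiples of the true read total also give whole reads, so the smallest total was taken at which the share of whole values came near its highest. At that total 58.3% to 68.8% of values lay within 0.05 reads of a whole number. The median share over all totals tried was at most 7.5% in any library. Depth ran from 28.4 to 46.9 M reads with a median of 34.4 M, and the RPKM values of a library summed to between 284379 and 294605. On simulated steps the depth was recovered within 0.16%. A count test was not used, since the values are RPKM and most genes have several exons.

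The log2 of RPKM plus 0.5 was tested for the 12399 genes with a mean of at least 1 RPKM over the 24 samples, which hold 99.51% of the RPKM. All fits used limma 3.58.1 in R 4.3.3, with the 4 groups in a single model, empirical Bayes with a trend in mean expression and robust settings, and a Benjamini-Hochberg adjusted p under 0.05. Fold changes are therefore on the log2(RPKM + 0.5) scale. The 7 comparisons were training within each genotype, genotype within each condition, their interaction, and training and genotype averaged over the other factor. Signs are trained minus home cage, Baf53b+/- minus wild type and, for the interaction, the response in heterozygotes minus that in wild type. Actl6b and the mean log2 value of each gene list were also compared by two-sided exact permutation tests over the 924 ways to split 12 animals, which can give no p below 0.00216.

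A total of 29 gene lists was fixed, and 27 had at least 5 tested members and entered the set tests. They were activity-induced early genes, glucocorticoid-responsive genes, heat shock and endoplasmic reticulum chaperones, BAF complex subunits, genes tied to BAF53b in neuron culture, excitatory postsynapse, presynaptic vesicle, actin and spine cytoskeleton and voltage-gated channel genes, interferon-stimulated genes, ribosomal proteins, the nuclear-encoded respiratory chain, neighbours of Actl6b on chromosome 5, sex-linked genes, and markers of interneurons, oligodendrocytes, astrocytes, microglia, endothelial and mural cells, choroid plexus, blood, meninges and fibroblasts, thalamus, striatum, CA1, CA3, dentate gyrus and immature neurons. A list of mitochondrially encoded genes matched 0 symbols and was not analysed here. Lists were tested with camera (preset correlation of 0.01, repeated with the estimated correlation) and with fry, adjusted over the 27 lists of a comparison, and members were also adjusted over the list alone. Early genes were the 1 list called with an estimated correlation in each genotype, joined by the glucocorticoid list in the average over genotypes. Some lists share members. Among others, Per1 and Errfi1 are on both the early gene and glucocorticoid lists, Srf on the early gene and actin lists, and Nptx2 on the early gene and neighbour lists. Calls of such genes are not separate results.

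Genes are named by a fixed rule. Actl6b is named in each comparison. Of the genes that passed, the 10 with the largest rise and the 10 with the largest fall could be named, or all of them where fewer than 10 passed, with up to 5 more by p that did not pass. In each list up to 4 members that passed, or else up to 2 by p, could be named. Fos, Arc, Egr1, Npas4, Nr4a1, Junb, Dusp1 and Bdnf were named whatever their p. Within the rule, calls that held when any single library was left out were preferred. Any gene named outside it is said to have been chosen after its values were seen.

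The fit was tested on simulated data for training in wild type. Of the genes changed among 12399, it recovered 74.6% of 67 at 1.2-fold, 95.5% of 67 at 1.5-fold and 100% of 66 at 2-fold, with 9 false calls and 0 in a comparison left untouched. Replicates were compared before averaging, and no pair of libraries held the same values (highest correlation of log values 0.996). Sex was called from Ddx3y, at a threshold of 1 RPKM, as 14 males and 10 females. Alternatives covered the pseudocount, the filter on low values, scaling between samples, sample weights, the model, sex as a covariate, the set test's correlation, each library left out in turn and, added after the data were seen, choroid plexus content, libraries that stood apart and the region around Actl6b. Splits of the samples were drawn 100 times with a fixed seed. Figures were drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.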

Results

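Gene expression was measured by RNA sequencing in the dorsal hippocampus of 24 mice, 1 library per animal, in 4 groups of 6. Wild-type C57BL/6J mice and mice heterozygous for a targeted allele of Actl6b were either taken from the home cage or killed 30 minutes after training in the object location memory task, in which a mouse explores an arena with objects at fixed places. Actl6b encodes BAF53b, an actin-related subunit found in the neuronal form of the BAF complex, which remodels chromatin. The heterozygotes are called Baf53b+/- here. The design asks whether hippocampal expression differs with a reduced dose of BAF53b at rest, after training, or in the response to training. The labels name a second mouse strain in the background of the heterozygotes alone. Strain background therefore goes with genotype in every genotype and interaction comparison. Differences between genotypes thus cannot be assigned to the dose of BAF53b alone. Home cage animals are the only controls. The response to training therefore cannot be divided into learning and the rest of the experience, such as exploring the arena. The values were RPKM (reads per kilobase of gene, scaled to the read total), and steps in the low values placed the depth of the libraries between 28.4 and 46.9 M reads. Mean depth was 34.5 ± 1.5 M reads (SD, n = 6) in wild-type home cage animals and 33.9 ± 3.7 M in trained wild-type animals. In the heterozygotes it was 37.2 ± 5.2 M in the home cage and 32.7 ± 2.0 M after training. A gene of 2 kb at 1 RPKM was thus covered by 56.8 to 93.8 reads.

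Actl6b itself, on chromosome 5 at 137994783 to 138010801 (mm9), was lower in every heterozygote than in every wild-type animal. Its level was 51.3 ± 1.26 RPKM in wild-type home cage animals and 50.8 ± 2.65 in trained wild-type animals (SD, n = 6). In heterozygotes it was 30.0 ± 1.44 RPKM in the home cage and 28.3 ± 1.47 after training, or 58.5% and 55.7% of the wild-type mean. The lowest wild-type library stood at 46.4 RPKM and the highest heterozygote at 32.4. A two-sided exact permutation test gave p = 0.00216 for the genotype difference in each condition, the smallest value that 6 against 6 animals can give. Training left no detectable difference in Actl6b in wild type (exact permutation p = 0.712) or in heterozygotes (exact permutation p = 0.0758). The part of the gene removed by the allele is not given in the sources used here, and the RPKM covers the gene as a whole.

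**Figure D1:**
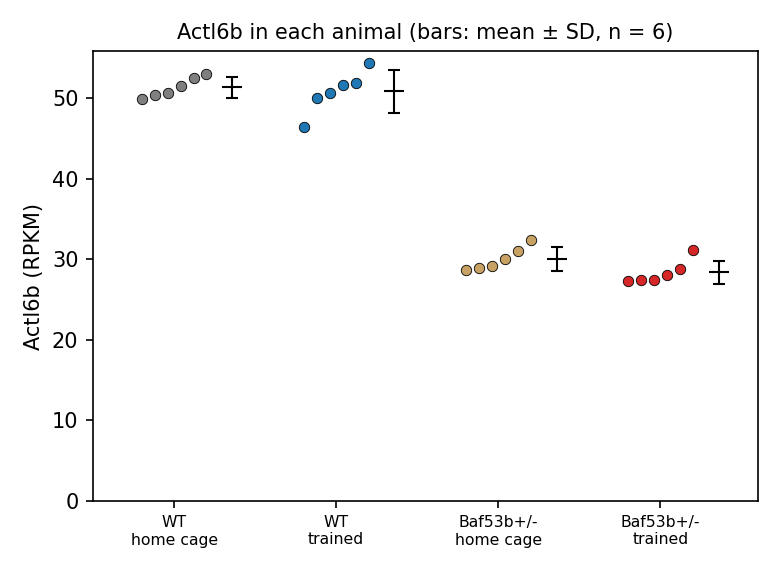
Actl6b level in RPKM (vertical axis, from 0) for each animal in the 4 groups, with points for animals and bars for mean ± SD (n = 6). The 12 heterozygotes all lie below the 12 wild-type animals, at 32.4 RPKM or less against 46.4 or more.

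Training in wild-type mice raised 33 of the 57 tested genes of a list that neurons induce when they fire. Fos, a transcription factor widely used as a marker of neuronal activity, rose from 1.89 ± 0.687 to 14.3 ± 4.58 RPKM (SD, n = 6), a 7.56-fold difference of the means. Arc, whose product acts in the trafficking of glutamate receptors at synapses, rose from 32.9 ± 7.83 to 124 ± 28.9 RPKM, and the zinc finger factor Egr1 rose from 45.1 ± 3.77 to 105 ± 9.56. Another zinc finger factor, Egr2, rose from 0.314 ± 0.136 to 2.86 ± 0.852 RPKM, or 9.13-fold. The nuclear receptor Nr4a1, the activity-dependent factor Npas4, the AP-1 members Junb and Fosb, the phosphatase Dusp1 and the kinase Sik1 also rose. For each of these 10 genes all 6 trained animals lay above all 6 home cage animals. Bdnf, a neurotrophin, stood at 10.1 ± 0.468 RPKM in the home cage and 10.8 ± 1.22 after training and did not pass the test.

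On the log2(RPKM + 0.5) scale, which understates the change of genes with low RPKM, limma gave Fos a difference of 2.63 ± 0.18 (SE; Benjamini-Hochberg adjusted p = 2.75e-09), Egr2 2.03 ± 0.13 (adjusted p = 4.72e-10), Arc 1.89 ± 0.15 (adjusted p = 1.53e-08) and Egr1 1.21 ± 0.07 (adjusted p = 7.74e-11). Differences were 1.40 ± 0.10 for Nr4a1, 1.29 ± 0.23 for Npas4, 1.14 ± 0.08 for Junb, 1.11 ± 0.12 for Fosb, 1.08 ± 0.11 for Dusp1 and 1.01 ± 0.10 for Sik1, with adjusted p from 2.29e-09 (Nr4a1) to 0.00386 (Npas4). Bdnf differed by 0.09 ± 0.07 (adjusted p = 0.695). In all, 119 of 12399 genes tested rose and 15 fell in wild type, and 23 of those that rose did so by over 1.5-fold. Among the genes that fell were Hes1, a transcriptional repressor of the Notch pathway, which fell by 0.40 (SE 0.08, adjusted p = 0.0115), and Lcmt2, which fell by 0.27 (SE 0.06, adjusted p = 0.0146). Mirlet7c-2, a microRNA precursor on chromosome 15 at 85537033 to 85537127, fell by 0.78 (SE 0.16, adjusted p = 0.00916), and the uncharacterised gene 2310061J03Rik fell by 0.32 (SE 0.07, adjusted p = 0.0137). A gene as short as Mirlet7c-2 has fewer reads behind a given RPKM than longer genes.

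Of the 60 genes fixed as activity-induced early genes, 57 were tested in wild type, of which 33 rose and 24 did not pass (47 rose when adjusted over the list alone). The list stood above other genes by camera (adjusted p = 1.91e-77; adjusted p = 4.69e-07 with an estimated correlation). Among 17 glucocorticoid-responsive genes, 5 rose (9 adjusted over the list alone), including the clock gene Per1 (0.45 ± 0.05, SE), the NF-kappaB inhibitor Nfkbia (0.41 ± 0.06), the glucocorticoid-induced leucine zipper gene Tsc22d3 (0.46 ± 0.09) and the mTOR inhibitor Ddit4 (0.36 ± 0.07). The glucocorticoid list, which shares Per1 and Errfi1 with the early gene list, gave a camera adjusted p of 2.31e-10, and adjusted p = 0.06 with an estimated correlation. Fry gave it an adjusted p of 0.00096. Its mean log2 value had an exact permutation p of 0.00216, not adjusted over lists. Of 24 heat shock and endoplasmic reticulum chaperones, the co-chaperone Dnajb1 rose (0.44 ± 0.05; 3 genes adjusted over the list alone), with a camera adjusted p of 1.19e-05 and adjusted p = 0.382 with an estimated correlation. Fry gave the chaperones an adjusted p of 0.0614. Their mean log2 value had an exact permutation p of 0.00649, not adjusted over lists. The transcription factor Sox11 rose (0.31 ± 0.07, adjusted p = 0.014) among 8 markers of immature neurons and proliferation (1 adjusted over the list alone; camera adjusted p = 0.219). No gene of the excitatory postsynapse list passed limma (0 of 46, 7 at an unadjusted p under 0.05). Camera placed the list lower as a set at adjusted p = 0.00107, with adjusted p = 0.382 with an estimated correlation. Leaving out the 6 libraries rich in choroid plexus transcripts, described further on, gave 65 called genes in wild type in place of 134, with the direction kept in all 134, and a fit of the wild-type groups alone gave 75. With the choroid plexus score as a covariate and all libraries kept, 141 genes were called, 128 of them among the 134.

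**Figure D2:**
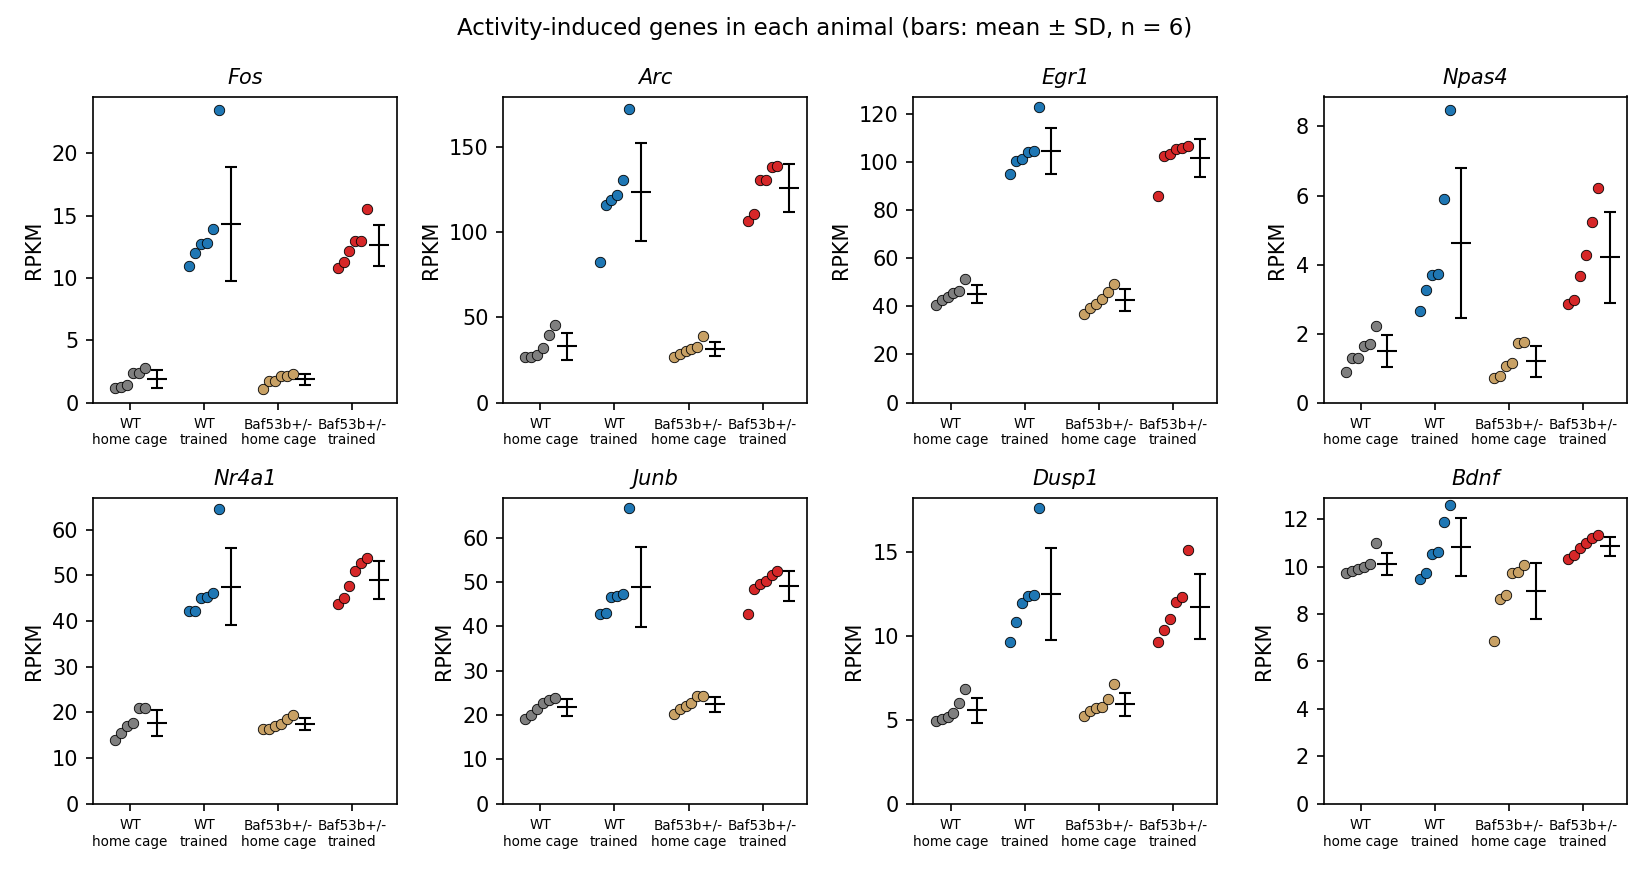
RPKM of 8 activity-induced genes fixed in advance (vertical axes, from 0) in each animal of the 4 groups, with points for animals and bars for mean ± SD (n = 6). For Fos, Arc, Egr1, Npas4, Nr4a1, Junb and Dusp1 every trained animal lies above every home cage animal of its genotype, and for Bdnf the wild-type groups overlap.

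Training in Baf53b+/- mice raised 34 of the 57 tested early genes, 29 of which also rose in wild type. Fos rose from 1.86 ± 0.44 to 12.6 ± 1.67 RPKM (SD, n = 6), or 6.78-fold, Arc from 31.5 ± 4.28 to 126 ± 14.0, and Egr1 from 42.5 ± 4.52 to 102 ± 7.94. Egr2 rose from 0.243 ± 0.108 to 2.87 ± 0.436 RPKM and Egr4, of the same zinc finger family, from 9.28 ± 0.44 to 19.4 ± 1.11. All 6 trained heterozygotes lay above all 6 home cage heterozygotes for Fos, Egr2, Arc, Npas4, Nr4a1, Egr1, Fosb, Junb, Egr4 and Dusp1. Bdnf stood at 8.97 ± 1.18 RPKM in the home cage and 10.9 ± 0.39 after training.

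With limma, the log2 differences in heterozygotes were 2.49 ± 0.18 for Fos (SE; Benjamini-Hochberg adjusted p = 5.76e-09), 2.18 ± 0.13 for Egr2 (adjusted p = 9.73e-11), 1.99 ± 0.15 for Arc (adjusted p = 5.84e-09) and 1.25 ± 0.07 for Egr1 (adjusted p = 3.6e-11). They were 1.47 ± 0.23 for Npas4 (adjusted p = 0.00108), 1.45 ± 0.10 for Nr4a1, 1.21 ± 0.12 for Fosb, 1.11 ± 0.08 for Junb, 1.02 ± 0.07 for Egr4 and 0.92 ± 0.11 for Dusp1. Bdnf differed by 0.27 ± 0.07 (adjusted p = 0.0689) and passed only when wild-type trained animal 2433 or heterozygous home cage animal 2401 was left out, at an adjusted p of 0.041 or more. In all, 110 genes rose and 18 fell, 21 of those that rose by over 1.5-fold. Hes1 fell by 0.45 (SE 0.08, adjusted p = 0.00383) and Chpf2, a gene of chondroitin sulfate synthesis, fell by 0.28 (SE 0.06, adjusted p = 0.00824). Agxt2l1, which encodes a phospholyase, fell by 0.59 (SE 0.13, adjusted p = 0.0145), a call that ended without trained animal 2435 (adjusted p = 0.0507). The call for Lcmt2, which fell by 0.26 (SE 0.06, adjusted p = 0.0196), ended without home cage animal 2424 or trained animal 2414 or 2435, with an adjusted p of up to 0.0703.

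Of the 57 early genes tested, 34 rose in heterozygotes and 23 did not pass (46 rose when adjusted over the list alone), with a camera adjusted p of 3.52e-87 and adjusted p = 1.74e-07 with an estimated correlation. Among the 17 glucocorticoid-responsive genes, 4 rose (7 adjusted over the list alone): Per1 by 0.41 ± 0.05 (SE), Ddit4 by 0.47 ± 0.07, Nfkbia by 0.37 ± 0.06 and Errfi1, an inhibitor of EGF receptor signalling, by 0.27 ± 0.06. Per1 and Errfi1 are also on the early gene list. For the glucocorticoid list the camera adjusted p was 4.29e-08, and adjusted p = 0.0952 with an estimated correlation. Fry gave it an adjusted p of 0.00627. Its mean log2 value had an exact permutation p of 0.00649, not adjusted over lists. Dnajb1 rose among the 24 chaperones (0.35 ± 0.05; 2 genes adjusted over the list alone; camera adjusted p = 0.000302, adjusted p = 0.701 with an estimated correlation). Fry gave the chaperones an adjusted p of 0.24. Their mean log2 value had an exact permutation p of 0.039, not adjusted over lists. Srf, the transcription factor that controls many actin genes, rose among the 43 genes of the actin and spine cytoskeleton (0.19 ± 0.04, adjusted p = 0.0171; 2 genes adjusted over the list alone), a call that ended without trained animal 2414 (adjusted p = 0.0576). Srf is also on the early gene list.

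Among markers of other cells and regions, 16 of 18 endothelial and mural markers had a positive difference in heterozygotes after training, though none passed limma (0 of 18, 3 at an unadjusted p under 0.05). The camera adjusted p was 0.00327, and adjusted p = 0.77 with an estimated correlation. Without home cage animal 2400 the camera adjusted p was 0.0532. All 14 dentate gyrus markers had a positive difference (median 0.17; 0 past limma, 2 at an unadjusted p under 0.05), with a camera adjusted p of 0.00911 and adjusted p = 0.881 with an estimated correlation. Without home cage animal 2415, whose dentate markers were the lowest of its group, the median was 0.026, 9 of 14 markers were positive and camera gave an adjusted p of 0.644. Sox11 rose among 8 markers of immature neurons and proliferation, as in wild type (0.29 ± 0.07, adjusted p = 0.0221), a call that ended without home cage animal 2401 or 2424 or trained animal 2416, 2429 or 2435 (adjusted p up to 0.0764). That list gave a camera adjusted p of 0.00919, and adjusted p = 0.062 with an estimated correlation. The 84 nuclear-encoded respiratory chain genes were lower as a set (median -0.03; 0 past limma, 5 at an unadjusted p under 0.05; camera adjusted p = 0.0425, adjusted p = 0.903 with an estimated correlation). That call ended without home cage animal 2415, 2422 or 2424 or trained animal 2409, 2414 or 2435 (adjusted p up to 0.644). Without the 6 libraries rich in choroid plexus transcripts 52 genes were called in heterozygotes in place of 128, and the heterozygous groups fitted alone gave 84. By Ddx3y the home cage heterozygotes were 5 males and 1 female, and the trained ones 3 of each. With sex as a covariate 110 genes were called, 108 of them among the 128, and all 128 kept their direction.

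Averaged over the genotypes, the response to training covered 404 genes that rose and 113 that fell. The largest were again Fos (2.56 ± 0.13, SE), Egr2 (2.11 ± 0.09), Arc (1.94 ± 0.10), Nr4a1 (1.43 ± 0.07), Npas4 (1.38 ± 0.17) and Egr1 (1.23 ± 0.05), with limma Benjamini-Hochberg adjusted p from 2.11e-14 (Egr1) to 9.17e-06 (Npas4). Most of the other changes were small: 21 of the 517 called genes exceeded 1.5-fold, and the median called difference was 0.15. Hes1 fell by 0.42 (SE 0.06, adjusted p = 4.56e-05), and Cirbp, a cold-inducible RNA-binding protein gene, fell by 0.32 (SE 0.06, adjusted p = 0.000756). The endothelial transcription factor genes Sox18 and Sox17 fell by 0.30 (SE 0.06, adjusted p = 0.00584) and 0.26 (SE 0.06, adjusted p = 0.0121). Endothelial genes did not fall as a group: 15 of the 18 listed endothelial and mural markers had a positive difference (median 0.064). Chpf2 fell by 0.25 (SE 0.04, adjusted p = 0.000293) and was lower in all 6 trained animals than in any home cage animal in each genotype.

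By list, 45 of 57 early genes rose over the genotypes (50 adjusted over the list alone; camera adjusted p = 5.72e-89, adjusted p = 1.47e-07 with an estimated correlation). Bdnf was among them at 0.18 ± 0.05 (SE; adjusted p = 0.0394), but that call ended in 14 of the 24 fits that each left out 1 library, with an adjusted p of up to 0.0742. Of 17 glucocorticoid-responsive genes 8 rose, among them Per1 and Errfi1 of the early gene list, and also 8 adjusted over the list alone. The camera adjusted p was 4.98e-11, and adjusted p = 0.0472 with an estimated correlation. Among 24 chaperones, Dnajb1 (0.39 ± 0.04), Hspb1 (0.44 ± 0.09) and Hspa1a (0.33 ± 0.07) rose, and 7 genes did when adjusted over the list alone. Camera gave an adjusted p of 2.18e-06, with adjusted p = 0.303 with an estimated correlation, and fry gave an adjusted p of 0.00841. Hspa1a has a near-identical neighbour, and how reads shared between copies were counted is not given in the sources used here.

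Among 28 BAF complex subunits, Smarce1 rose (0.13 ± 0.03, SE; adjusted p = 0.00769) and Brd9 fell by 0.11 (SE 0.03, adjusted p = 0.0497), the same counts when adjusted over the list alone. The Brd9 call ended in 20 of the 24 fits that each left out 1 library (adjusted p up to 0.0831), and the list as a set did not pass camera (adjusted p = 0.798). The adhesion gene Nlgn1 fell by 0.13 (SE 0.03, adjusted p = 0.0172) among 46 excitatory postsynapse genes (1 lower adjusted over the list alone; camera adjusted p = 0.0688). Srf (0.17 ± 0.03), which is also on the early gene list, and the cofilin phosphatase Ssh2 (0.09 ± 0.02) rose among 43 actin genes (2 adjusted over the list alone; camera adjusted p = 0.944). Sox11 rose (0.30 ± 0.05) among 8 immature neuron and proliferation markers (1 adjusted over the list alone). That list had a camera adjusted p of 0.0344, which rose to as much as 0.0654 without wild-type home cage animal 2404 or heterozygous animal 2422 (home cage) or 2429 (trained), and adjusted p = 0.0802 with an estimated correlation. The interferon pathway factor Irf9 rose (0.21 ± 0.06, adjusted p = 0.0267) among 13 interferon-stimulated genes (1 adjusted over the list alone; camera adjusted p = 0.479), except when wild-type home cage animal 2430 or trained heterozygote 2416 was left out (adjusted p up to 0.0519). Of 59 neighbours of Actl6b on chromosome 5, 5 rose over the genotypes (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.233), among them Mepce (0.13 ± 0.02), Zscan21 (0.21 ± 0.04) and Smurf1 (0.14 ± 0.03).

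Markers of most cell types did not pass limma over the genotypes. Among the 18 endothelial and mural markers 15 had a positive difference, 5 had an unadjusted p under 0.05 and 0 passed. Camera placed the list higher at an adjusted p of 0.0374, and adjusted p = 0.915 with an estimated correlation. The camera call ended without wild-type animal 2402 or 2404 (home cage) or 2403, 2421 or 2433 (trained), or heterozygous animal 2400, 2415 or 2422 (home cage) or 2429 (trained), with an adjusted p of up to 0.149. No member passed among 21 oligodendrocyte, 17 astrocyte, 17 microglia and 17 interneuron markers, of which 1, 2, 2 and 1 had an unadjusted p under 0.05, nor among 14 choroid plexus and 12 meninges and fibroblast markers (0 each). The same held for 10 CA1, 9 CA3 and 14 dentate gyrus markers (1, 2 and 1 at an unadjusted p under 0.05) and for 13 thalamus and 8 striatum markers (1 and 0). No gene passed among 35 presynaptic vesicle genes, 42 voltage-gated ion channels, 64 cytosolic ribosomal proteins and 84 respiratory chain genes (2, 3, 1 and 3 at an unadjusted p under 0.05). Neither did any of 3 blood markers (1 at an unadjusted p under 0.05, lower when adjusted over the list alone) or 5 sex-linked genes (0). Of 5 genes tied to BAF53b in cultured neurons, 0 passed and 3 had an unadjusted p under 0.05, and 2 were lower when adjusted over the list alone. Camera gave adjusted p of 0.1 or more for these lists, apart from the endothelial list and the blood markers, which were too few for it.

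The responses of the genotypes were compared gene by gene. Of the genes called within a genotype, 65 were higher in both, where independent lists of those sizes would share 1.06, and 4 were lower in both, against 0.022. None was called in opposite directions. Of 65 genes called in wild type alone 64 had a difference of the same sign in heterozygotes, and of 59 called in heterozygotes alone 58 had the same sign in wild type. Across the 517 genes called on average, the heterozygous response regressed on the wild-type response with a slope of 0.953 (0.98 the other way) and a Pearson r of 0.956, taken across genes, which are not independent replicates. These genes were chosen for a response averaged over both genotypes, which favours agreement, and over all 12399 genes Pearson r was 0.402.

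**Figure D3:**
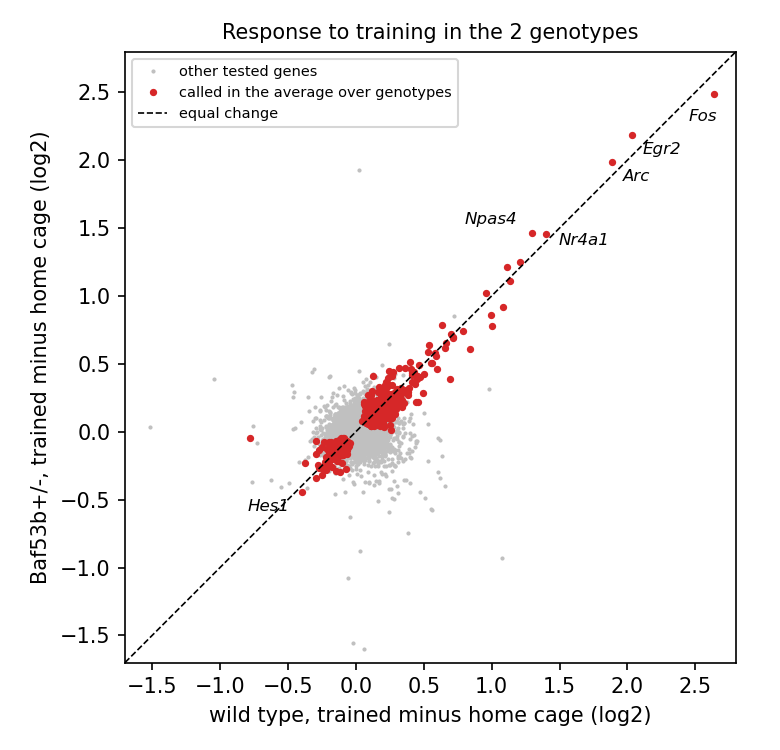
Log2 difference between trained and home cage animals in wild type (horizontal axis) and in Baf53b+/- mice (vertical axis), with 1 point per tested gene and the 517 genes called on average in red. The red points run along the dashed line of equal change, from Hes1 at the lower left to Fos at the upper right.

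Whether the response to training itself differed between genotypes was tested as an interaction, the response in heterozygotes minus that in wild type. No gene passed limma (0 of 12399; 309 at an unadjusted p under 0.05, where 620 would be expected by chance; smallest adjusted p 0.985). Among the early genes fixed in advance, the interaction was -0.15 ± 0.26 for Fos (SE, 95% interval -0.68 to 0.39), 0.10 ± 0.21 for Arc, 0.04 ± 0.10 for Egr1 (95% interval -0.16 to 0.25), 0.17 ± 0.33 for Npas4, 0.05 ± 0.14 for Nr4a1, -0.03 ± 0.12 for Junb, -0.16 ± 0.16 for Dusp1 and 0.18 ± 0.10 for Bdnf (95% interval -0.03 to 0.39). The mean log2 value of the 57 early genes was 3.39 ± 0.103 (SD, n = 6) in trained wild-type animals and 3.38 ± 0.033 in trained heterozygotes (two-sided exact permutation p = 0.935). In the home cage it was 2.83 ± 0.041 and 2.81 ± 0.026 (exact permutation p = 0.468). The difference in Actl6b itself between trained and home cage animals did not depend on genotype by this test (-0.07 ± 0.05, adjusted p = 0.985).

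The genes with the smallest unadjusted p in the interaction were Agxt2l1 (-0.83 ± 0.18, SE), the choline kinase gene Chkb (-0.39 ± 0.10), 5730469M10Rik (-0.21 ± 0.06), 6330416G13Rik (-0.29 ± 0.09) and 2310061J03Rik (0.32 ± 0.09), all at an adjusted p of 0.985. Agxt2l1 and 2310061J03Rik, called within a single genotype, were thus not shown to respond differently. The same held, each at an adjusted p of 0.985, for Mirlet7c-2 (0.73 ± 0.22), Tsc22d3 (-0.24 ± 0.12), Chpf2 (-0.06 ± 0.08), Errfi1 (0.05 ± 0.08) and Srf (0.05 ± 0.06). The precision was limited: the median 95% interval of an interaction reached 0.155 to either side, and 0.141 for the 517 genes called on average. For 511 of those 517 genes it excluded a 1.5-fold difference between the genotypes' responses. Only 21 of the 517 average responses themselves exceeded 1.5-fold, and their median size was 0.15. For most of these genes that bound thus cannot tell an equal response from a lost one.

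In the home cage, Actl6b was the 1 gene that passed between genotypes, with a log2 difference of -0.77 ± 0.04 (SE; limma, Benjamini-Hochberg adjusted p = 1.53e-12), lower in 6 of 6 heterozygotes. Of 12399 genes, 0 were higher and 1 was lower, and 437 had an unadjusted p under 0.05 where chance would give 620. The next genes by p did not pass: 4933404O12Rik stood at 3.39 ± 0.174 RPKM in wild type and 4.19 ± 0.208 in heterozygotes (SD, n = 6; log2 difference 0.27 ± 0.05, adjusted p = 0.199), and A430033K04Rik at 4.86 ± 0.316 and 4.03 ± 0.426 (-0.25 ± 0.06, adjusted p = 0.889). The glycoprotein folding sensor Uggt2 (-0.31 ± 0.08), the matrix metalloproteinase Mmp17 (-0.24 ± 0.06) and Tmem132d (0.48 ± 0.12) had an adjusted p of 0.999. Among the genes tied to BAF53b in cultured neurons, Ngef differed by 0.07 ± 0.05 and Rap1gap by 0.05 ± 0.04 (0 of 5 past limma, 0 at an unadjusted p under 0.05). In the BAF complex list Actl6b alone passed, over all genes and adjusted over the list alone. No early gene passed (0 of 57, 4 at an unadjusted p under 0.05, 0 adjusted over the list alone).

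Marker lists differed as sets in the home cage, with a preset correlation only. The 14 dentate gyrus markers all lay lower in heterozygotes (median -0.15; camera adjusted p = 0.000584, adjusted p = 0.609 with an estimated correlation). That difference rested on heterozygous animal 2415, without which the median was -0.006, 7 of 14 markers were positive and the camera adjusted p was 0.464. The 14 choroid plexus markers all lay higher (median 0.73; camera adjusted p = 0.00466, adjusted p = 0.648 with an estimated correlation). Their mean log2 value was 0.982 ± 1.14 in wild type and 1.78 ± 1.82 in heterozygotes (SD, n = 6; two-sided exact permutation p = 0.279). The camera call ended without heterozygous animal 2422 or 2424 (adjusted p up to 0.367, median 0.264). Of the 84 respiratory chain genes 73 lay higher (camera adjusted p = 0.000584, adjusted p = 0.648 with an estimated correlation), a call that ended without wild-type animal 2402 or heterozygous animal 2415 or 2422 (adjusted p up to 0.14). The 42 voltage-gated ion channels lay lower (median -0.03; camera adjusted p = 0.0478, adjusted p = 0.609 with an estimated correlation). Their call ended without wild-type animal 2402, 2404 or 2430, heterozygous animal 2400, 2415, 2422 or 2424, or trained heterozygote 2416 (adjusted p up to 0.203). The 3 blood markers had an unadjusted p under 0.05 and none passed over all genes. Adjusted over the list alone, 2 were higher and 1 lower. By Ddx3y the heterozygous home cage group held 5 males and 1 female, against 3 of each in every other group.

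After training, Actl6b was again the 1 gene that passed between genotypes (-0.83 ± 0.04, SE; limma, Benjamini-Hochberg adjusted p = 2.26e-13; lower in 6 of 6 heterozygotes), with 458 genes at an unadjusted p under 0.05. A430033K04Rik, on chromosome 5 at 139064087 to 139090054, was at the threshold, with 5.23 ± 0.39 RPKM in wild type and 4.09 ± 0.166 in heterozygotes (SD, n = 6; -0.32 ± 0.06, adjusted p = 0.05). It passed when wild-type animal 2405 (home cage) or 2421 (trained) or heterozygous home cage animal 2400, 2401 or 2424 was left out, and its adjusted p ranged from 0.0168 to 0.236 over all 24 omissions. Next came Mirlet7c-2 (0.66 ± 0.16), the phospholipase gene Pla2g4e (0.37 ± 0.09), Cdr1 (-0.43 ± 0.11) and the lipase gene Daglb (0.13 ± 0.03), each at an adjusted p of 0.993. Gap43, a growth cone protein gene tied to BAF53b in cultured neurons, stood at 71.3 ± 22.4 RPKM in wild type and 57.4 ± 8.62 in heterozygotes (-0.27 ± 0.21, adjusted p = 0.993), and Stmn2, which acts on microtubules, at 176 ± 11.1 and 163 ± 9.18 (-0.11 ± 0.06, adjusted p = 0.993).

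By camera with a preset correlation, 6 of 27 lists differed between trained genotypes and 0 did with an estimated correlation. Lists higher in heterozygotes were the endothelial and mural markers (camera adjusted p = 0.000243; adjusted p = 0.856 with an estimated correlation), the oligodendrocyte markers, all 21 of which had a positive difference (camera adjusted p = 0.0135; adjusted p = 0.923 with an estimated correlation), and the dentate gyrus markers (camera adjusted p = 0.0201; adjusted p = 0.923 with an estimated correlation). The meninges and fibroblast markers and the interferon-stimulated genes each gave a camera adjusted p of 0.0135, and adjusted p = 0.856 with an estimated correlation. The chaperones were lower at the same camera value and the same adjusted p = 0.856 with an estimated correlation. Of these 6 calls, the endothelial one held when any single library was left out (adjusted p up to 0.0393). The others ended without certain trained animals. For dentate markers these were wild-type 2403, 2412 or 2421 or heterozygous 2409, 2410 or 2435 (up to 0.301), and for oligodendrocyte markers wild-type 2403 or 2433 or heterozygous 2409, 2416 or 2435 (up to 0.432). For chaperones they were wild-type 2421 or heterozygous 2409, 2410 or 2435 (up to 0.301), for meninges markers wild-type 2407 or 2436 or heterozygous 2409 or 2429 (up to 0.214), and for interferon genes heterozygous 2409, 2416 or 2429 (up to 0.198).

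Averaged over the conditions, 3 genes differed between genotypes, all on chromosome 5. Actl6b was lower by limma (-0.80 ± 0.03, SE; Benjamini-Hochberg adjusted p = 1.91e-16), A430033K04Rik was lower (-0.28 ± 0.04, adjusted p = 0.00161; 11 of 12 heterozygotes below all wild-type animals), and 4933404O12Rik, at 137395016 to 137412979, was higher (0.22 ± 0.04, adjusted p = 0.0197; 5 of 12 heterozygotes above all wild-type animals). The last 2 start 1.1 Mb beyond and 0.6 Mb before Actl6b. The 4933404O12Rik call ended without wild-type home cage animal 2402, 2418 or 2425, wild-type trained animal 2403 or 2412, or heterozygous home cage animal 2424 (adjusted p up to 0.0562). Not past the threshold were Gnb2, a G protein subunit gene that lies next to Actl6b (-0.11 ± 0.02, adjusted p = 0.296), and, at an adjusted p of 0.419, Cdr1 (-0.32 ± 0.07), Tmem132d (0.37 ± 0.09), Cpsf4 (0.21 ± 0.05) and Arhgef6 (-0.17 ± 0.04). Arhgef6 passed without heterozygous home cage animal 2415 (adjusted p = 0.0406).

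The fixed list of Actl6b neighbours does not hold A430033K04Rik or 4933404O12Rik. Of its 59 tested genes, 0 passed over all genes in the average by limma (8 at an unadjusted p under 0.05), and 3 were higher and 2 lower when adjusted over the list alone. Camera gave that list an adjusted p of 0.0402, and adjusted p = 0.66 with an estimated correlation. The call ended in 12 of 24 single omissions: wild-type 2402, 2425, 2403, 2407, 2412 or 2421, or heterozygous 2401, 2415, 2424, 2416, 2429 or 2435 (adjusted p up to 0.135). Other lists called with the preset correlation were the endothelial and mural markers (higher; adjusted p = 0.777 with an estimated correlation), choroid plexus and meninges and fibroblast markers (both higher; adjusted p = 0.807 with an estimated correlation), interferon-stimulated genes (higher) and chaperones (lower), the last 2 at adjusted p = 0.777 with an estimated correlation. Each of these calls also ended when certain libraries were left out. The endothelial call ended without wild-type 2407 (adjusted p = 0.0508), the chaperone call without wild-type 2421 (0.0685), and the choroid plexus call without heterozygous 2422, 2424, 2409 or 2429 (up to 0.287). The meninges call ended without wild-type 2418, 2430, 2407 or 2436 or heterozygous 2401, 2422, 2409 or 2429 (up to 0.222), and the interferon call without wild-type 2430 or 2407 or heterozygous 2401, 2416 or 2429 (up to 0.14). In the tested genome the share of genes with an unadjusted genotype p under 0.05 was 9.1% on chromosome 5 and between 2.5% and 6.2% on each other autosome and X.

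**Figure D4:**
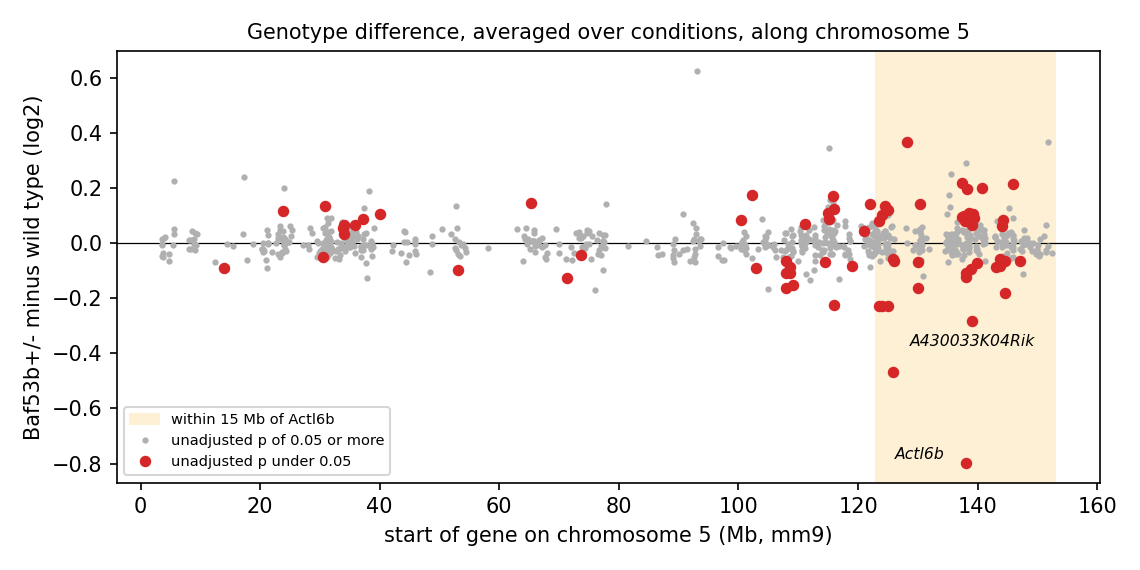
Log2 difference between Baf53b+/- and wild-type mice averaged over conditions (vertical axis) against the start of each tested gene on chromosome 5 in Mb of mm9 (horizontal axis), with 1 point per gene and red for an unadjusted p under 0.05. Within 15 Mb of Actl6b (shaded) 38 of 269 other genes are red, and Actl6b lies lowest at -0.80.

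Libraries also differed in choroid plexus transcripts, with libraries rich in them in all 4 groups. Ttr, the transthyretin gene that choroid plexus epithelium expresses very strongly, ranged from 7.78 to 4571.6 RPKM. It exceeded 1000 RPKM in 6 libraries, wild-type home cage 2425, wild-type trained 2412, heterozygous home cage 2422 and 2424, and heterozygous trained 2409 and 2429, and was at most 288.3 in the other 18. The principal component that carried 24.3% of the variance placed these 6 libraries at 1 end. Wild-type trained animal 2421 lay furthest out on the component carrying 14.3%, and heterozygous home cage animal 2415 on that carrying 10.3%. Without the 6 libraries, 237 of the 262 genes called for training over the genotypes were also called with all libraries, and all 517 kept the direction of their difference.

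**Figure D5:**
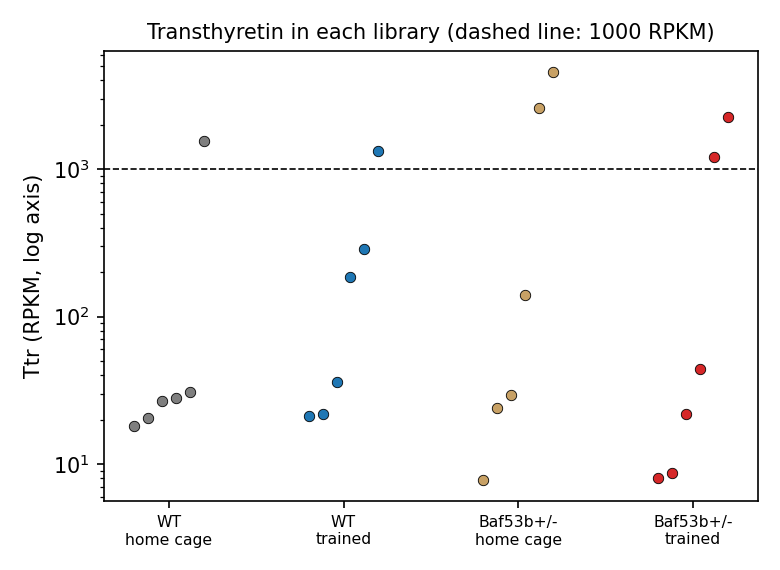
Ttr level in RPKM (vertical axis, log scale) in each library of the 4 groups, with 1 point per animal. The dashed line marks 1000 RPKM, and the 6 libraries above it come from all 4 groups.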

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

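Chosen only after the results were seen were the tests of position, of direction and of genes elsewhere on the chromosome 5 pattern and all tests on choroid plexus transcripts. The splits of the samples and the test of unequal sexes were set beforehand, though the splits for chromosome 5 used the window of the position test.

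Other splits of the animals rarely gave as many called genes as training. For training in wild type, 1 of 100 splits, the real one with 134 genes, gave as many (highest other 74), and for training in heterozygotes again 1 of 100 (128 genes, highest other 2). Averaged over the genotypes it was 1 of 100 (517 genes, highest other 31), so chance can be excluded for these counts. For genotype, 4 of 100 splits in the home cage gave as many as the real 1 gene, and the other 3 of these called 23, 13 and 3. Such counts may come from structure among those 12 libraries other than genotype, which was not tested; chance can be excluded for the count only narrowly. After training 5 of 100 splits gave as many as the real 1 gene (highest other 1), so chance cannot be excluded for that count as such. The gene counted in each condition is Actl6b, the targeted gene, for which the adjusted p of 1.53e-12 and 2.26e-13 and the separation of all 12 heterozygotes exclude chance. Averaged over conditions 1 of 100 splits, the real one, gave as many (3 genes, highest other 2). Actl6b, the targeted gene, is 1 of the 3. The count thus does not exclude chance for A430033K04Rik and 4933404O12Rik, whose calls rest on their own adjusted p. For the interaction the real count was 0 (highest other 2). Every split must give at least 0, so the splits cannot test it.

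Small genotype differences gathered around Actl6b on chromosome 5. Within 15 Mb, 38 of 269 genes other than Actl6b (14.13%, exact 95% interval 10.19% to 18.87%) had an unadjusted p under 0.05. Elsewhere 518 of 12129 did (4.27%, Fisher's exact test, two-sided p = 2.78e-10). Of 100 regroupings, the real one included, 3 gave as large a share (highest other 15.99%). They used the window of the position test, which was chosen after the results were seen, and do not allow for that choice. Chance is thus not excluded. The share of 4.27% elsewhere, below the interval of 10.19% to 18.87%, argues against an effect of BAF53b loss at any position as the whole cause. Of the 38 genes, 19 were lower (50%, exact 95% interval 33.4% to 66.6%). That argues against reads lost to strain variants as the whole cause, since such loss would make most of them lower. Lost reads in some of the genes are not excluded. Both intervals take the genes as independent, though they were measured in the same animals and a regrouping reached 15.99%. The intervals may thus be too narrow, and both arguments are weaker for it. A candidate explanation is DNA of a second mouse strain linked to the targeted allele, which the labels name in the heterozygotes' background alone. It cannot be told apart from an effect of the altered Actl6b locus on its neighbours, because the allele and the linked DNA go together in all 12 heterozygotes.

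Ttr and choroid plexus genes varied between libraries, and the 6 richest libraries came from all 4 groups. In all 6 libraries with Ttr above 1000 RPKM the mean log2 value of the other 13 markers (at least 2.35) lay above that of each of the other 18 (at most 0.998). The markers given next were chosen after their values were seen. Kl was at 17.6 to 43.1 RPKM in these 6 against 4.44 to 9.54, Folr1 at 8.25 to 25.0 against 0.14 to 2.06, Clic6 at 7.64 to 25.1 against 0.29 to 2.52 and Aqp1 at 1.81 to 9.31 against 0.04 to 0.7. In these libraries the markers thus rose together. This may come from choroid plexus carried along in some dissections, which would bring all its abundant transcripts together. Genotype and training stay open as contributors, with smallest exact permutation p of 0.279 and 0.6, too few animals to decide.

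With a preset correlation, 7 gene lists had an interaction of genotype and training by camera, although no single gene did. The median log2 interactions were 0.242 for dentate gyrus markers, 0.106 for oligodendrocyte markers, 0.058 for endothelial and mural markers, 0.038 for voltage-gated channels, 0.026 for the excitatory postsynapse, 0.021 for actin genes and -0.041 for the respiratory chain, with camera adjusted p from 9.25e-06 to 0.0486. The dentate median was 0.104 without heterozygous home cage animal 2415 and 0.317 without wild-type home cage animal 2418, and its call held in all 24 single omissions, while each of the other 6 ended in at least 2 of them, with medians from 0.023 to 0.236 (oligodendrocyte), 0.018 to 0.091 (endothelial), 0.024 to 0.06 (channels), 0.016 to 0.04 (postsynapse), 0.014 to 0.036 (actin) and -0.06 to -0.026 (respiratory chain). With an estimated correlation each had an adjusted p of 0.819, and 58 of 100 regroupings gave as many lists as the real 7 (median 7, highest other 11), so chance cannot be excluded. With sex as a covariate 7 lists were called, a count that regroupings reach as well and that leaves unequal sexes open, and the lists may reflect genes that vary together between animals, such as the dentate markers with their estimated correlation of 0.749.

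Single animals lay far from the other 5 of their group in 29 of 360 tests, where chance marks about 1 in 20 groups, or 18, and 10 animals were involved. Trained wild-type animal 2436 was the highest of its group for Fos (23.43 RPKM), Egr2 (4.546), Nr4a1 (64.46), Egr1 (122.9), Junb (66.61) and Dusp1 (17.61), for the mean log2 value of the early genes (3.601) and for that of the Actl6b neighbours (3.551). Trained heterozygote 2409 was low in Egr1 (85.73 RPKM). Heterozygous home cage animal 2415 was high in Gap43 (130.6 RPKM), Stmn2 (213.6), Rap1gap (60.37) and Arhgef6 (6.28) and in the mean log2 value of the genes tied to BAF53b in culture (6.345), and low in that of the actin genes (5.321) and the dentate markers (3.291). Dentate markers were also low in wild-type home cage animal 2418 (3.747) and trained heterozygote 2416 (3.907).

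Wild-type home cage animal 2418 was also high in Nfkbia (11.5 RPKM) and Tsc22d3 (17.76) and low in the mean log2 value of the BAF subunits (4.158). The same animal's omission gave 160 called genes for training in wild type. Wild-type home cage animal 2404 was high in Bdnf (11.01 RPKM) and animal 2425 in the mean log2 value of choroid plexus markers (3.283). Among trained wild-type animals, 2421 was high in Agxt2l1 (5.65 RPKM) and in the mean log2 value of the chaperones (4.703), and 2403 was high in Brd9 (39.41 RPKM). Heterozygous home cage animal 2401 was low in Cirbp (25.48 RPKM) and high in Uggt2 (3.448). Trained heterozygote 2416 was high in the mean log2 value of microglia markers (4.05).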

How the results depend on the processing

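The comparisons, tests, gene lists and most alternatives were chosen before the data were examined. The choroid plexus covariate, the fits without 6 or 2 libraries and the fit without genes within 15 Mb of Actl6b were chosen after, as were single omissions for lists not first chosen for them. No paired analysis was possible because each replicate number belongs to 1 animal in 1 group. Among called genes picked by the naming rule, 0 of 1127 values under alternatives other than single omissions and 0 of 2208 under single omissions changed direction. These genes were chosen for passing the test, and calls that held under single omissions were preferred, which favours such counts. Among all genes so picked, called or not, 4 of 1611 and 7 of 3168 values changed direction. The alternatives rescaled, reweighted or dropped libraries and genes, and limma's interaction count was 0 in each.

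Counts moved by over 1.5 times as follows. With a mean of at least 5 RPKM, which tests fewer genes, 83 genes were called for training in wild type, 84 in heterozygotes and 339 on average, and 1 for genotype averaged over conditions. Fitting only the groups compared, with fewer animals behind the spread, gave 75 and 84 for training in wild type and heterozygotes. Without the 6 libraries with Ttr over 1000 RPKM, which left 18 animals, training called 65 genes in wild type, 52 in heterozygotes and 262 on average. With the choroid score as a covariate and all animals kept, these counts moved by less (141, 126 and 571). With sex as a covariate they were 134, 110 and 471. Genotype averaged over conditions called 5 genes without a filter and 1 without the genes within 15 Mb of Actl6b, which drops its neighbours. Genotype after training called 2 genes in place of 1 with a pseudocount of 1, median-of-ratios scaling, sample weights, no trend and no robust settings, without the chromosome 5 neighbour list, and without the 2 libraries apart on components 2 and 3. Leaving out single libraries it called 1 or 2. The added gene was A430033K04Rik, whose adjusted p sits at the threshold, and the cause was not tested. With an estimated correlation 4 list calls were left over the 7 comparisons in place of 39.

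Differences near 0 changed sign without passing, and the cause was not tested. The Junb interaction was 0.001 with sample weights and 0.053 without the 6 libraries (single omissions -0.061 to 0.066). Arc's was -0.014 without the 2 libraries (single omissions -0.014 to 0.197), and that of Fos ran from -0.253 to 0.002, the latter without trained wild-type animal 2436. Actl6b's training difference in wild type was 0.006 without the 6 libraries (single omissions -0.035 to 0.011). Leaving out single libraries, called genes ran from 92 to 160 for training in wild type, 96 to 142 in heterozygotes and 415 to 541 on average. Depth limits the 7262 genes under the filter, where 1 RPKM on 2 kb is at most 93.8 reads in any library, and fewer on shorter genes.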

Other observations

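The genes named in the next paragraph, and the pair of chromosome 5 genes after it, were chosen after their values were seen; no test of an explanation was run on them.

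Below the expression filter, further genes passed for training, among them Atf3 and Maff of the early gene list. Most of them are not on that list. When all 19661 genes were tested by limma, 36 of the 7262 with a mean under 1 RPKM passed on average over the genotypes (23 higher, 13 lower). Atf3, a stress-induced transcription factor on the early gene list, rose by 0.44 ± 0.06 on the log2(RPKM + 0.5) scale (SE; Benjamini-Hochberg adjusted p = 6.37e-05), from 0.486 to 0.665 RPKM in wild type and from 0.426 to 0.934 in heterozygotes. Mir132, the precursor of a microRNA controlled by CREB, rose by 0.73 ± 0.14 (adjusted p = 0.00354), from 0.388 to 1.19 RPKM in wild type and from 0.349 to 0.801 in heterozygotes. RPKM is scaled by length, so these values of a short precursor stand for few reads. Reads of an overlapping transcript cannot be told apart from its own. Gem, a small GTPase that restrains calcium channels, rose by 0.34 ± 0.07 (adjusted p = 0.00804), the small Maf factor Maff by 0.22 ± 0.06 (adjusted p = 0.0416), the Notch ligand Dll4 by 0.30 ± 0.05 (adjusted p = 0.00204) and the urokinase receptor Plaur by 0.25 ± 0.06 (adjusted p = 0.0121). Within a single genotype, 8 genes under the filter passed in wild type and 5 in heterozygotes.

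Without the filter, 5 genes differed between genotypes on average and all lay on chromosome 5. Besides the 3 called above the filter these were Fzd10, a Wnt receptor gene, and 5930412G12Rik, whose starts both lie 8.9 Mb before Actl6b. Fzd10 stood at 0.239 ± 0.0539 RPKM in wild-type home cage animals and 0.188 ± 0.0709 after training, against 0.749 ± 0.409 and 0.822 ± 0.25 in heterozygotes (SD, n = 6; limma log2 difference 0.80 ± 0.13, SE, Benjamini-Hochberg adjusted p = 0.0106). For 5930412G12Rik the values were 0.51 ± 0.137 and 0.529 ± 0.0935 in wild type and 0.945 ± 0.326 and 1.08 ± 0.272 in heterozygotes (0.55 ± 0.10, adjusted p = 0.0436).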
